A study of Oryza sativa with 2 samples.

How the data were processed

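Total RNA from leaves of 4-week-old rice seedlings was compared between an OsRDR1 mutant and the wild type on 2 two-colour Agilent oligonucleotide arrays. Per the labels, the arrays are biological replicates 1 and 2. On replicate 1 the mutant RNA carried Cy5 and the wild-type RNA Cy3, and on replicate 2 the dyes were swapped. Nothing in the sources used here says how many plants each RNA came from or whether they were grown apart, so the spread between these arrays may be technical. The p-values of probes rest on that spread, mostly pooled over probes. Those of the gene lists, tested with camera at a preset correlation, rest on the spread among genes. Neither may measure the spread between plants. Dye orientation, slide and scan each differ between the 2 arrays, so none of them can be separated from the replicate.

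The deposited scanner files hold spot intensity values on a linear scale, quantified with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. Mean spot intensity and median local background intensity are uncorrected, per the file headers. The same files hold processed intensities, which per the file headers were background-subtracted, spatially detrended and dye-normalized by the scanner software, and a log10 ratio of Cy5 over Cy3. The authors' value table holds that log10 ratio to within 0.00500 on both arrays, in the Cy5 over Cy3 direction on each, with a median of 0 in both columns. Its scale, centring and direction were settled by this match. On replicate 1 it is therefore mutant over wild type and on replicate 2 the reverse.

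Spot signals were corrected with normexp and an offset of 50 and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The resulting log2 ratio, computed here from the deposited intensities, was turned to mutant over wild type on both arrays. Control spots were left out, as were spots marked as non-uniform (14 on replicate 1 and 9 on replicate 2). No spot was saturated. A probe was kept when it was well above background in at least 1 channel on both arrays, and replicate spots were averaged. Of 42418 probes that were not controls, 31487 were tested, and 31352 of these named a locus, for 21390 genes. Each probe was fitted with limma with the sign of the mutant dye as the design, followed by eBayes and Benjamini-Hochberg adjustment over all probes, with a threshold of 0.05. The fit left 1 residual degree of freedom per probe beside a prior of 16.3. A dye term could not be fitted, because genotype and dye together leave 0 degrees of freedom within arrays.

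The number of arrays limits the precision. On simulated arrays with 31487 probes, of which 200 were changed, the test recovered 6 of 50 probes changed by 1.25-fold, 42 of 50 changed by 1.5-fold, and 50 of 50 changed by 2-fold and by 4-fold. In the same simulation 20 of 168 calls were false, a share of 11.9% and above the nominal threshold. Its probes were independent, with spreads drawn from the fitted prior. Since 26.7% of the real probes were called, against 200 probes changed here, this share need not carry over to them. With a dye effect added to each probe, 20 of 166 calls were false. Its SD was 0.05 on the log2 scale, below the prior SD of 0.155, and larger dye effects were not simulated. With no probe changed, 0 probes were called, and 3 with the dye effect. For the gene lists, a simulation over 21390 genes with no list shifted called 0 of 28 lists. Its genes were independent of each other, so it could not show false calls that come from correlated genes.

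Locus identifiers and descriptions are those of the array design and can be old. Symbols were attached by locus identifier from the gene lists. The reference gene table was not used for names, since 0 of 29689 array loci matched its identifiers, and no coordinates are printed. Each gene was represented by its probe with the highest mean intensity over both arrays. The 28 gene lists were filled from locus identifiers and words in the descriptions. In all 559 loci whose description matched such a word but named another product were dropped, after the descriptions were read and before any ratio was computed. Of these 378 were from the cell cycle list, 46 from the seed storage list, 43 from the NB-ARC list, 36 from the pathogenesis-related list and 31 from the meristem and flower list. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run beside it. With an estimated correlation, camera has only the 1 residual degree of freedom left by 2 arrays, and so has fry. Camera could then hardly call any list, so its p-values do not decide whether a call holds. Calls within a list were also adjusted over the list alone.

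The genes named were fixed by rule. They are OsRDR1, the 12 highest and 12 lowest annotated genes past the threshold with the same sign on both arrays, up to 4 members of each list with the largest change and the same sign on both arrays, and the RNA-dependent RNA polymerase, Dicer-like and Argonaute genes as a group. A probe not well above background on either array of a genotype was given a bound: the mean log2 signal of the brighter genotype against, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal, after loess and Aquantile normalization.

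The words and locus identifiers of the gene lists, the tests of probes and lists, the rule for named genes and the alternatives were chosen before the data were examined, with exceptions. The dropped loci were chosen after the descriptions were read. The test of dye bias, the comparison of gene families, the lists with no locus dropped, the counting spread asked of the test of tandem families, and the rule that lists not called also count as turned were chosen after results were seen. The alternatives covered the background correction, the normalization, the source of values, the filter on dim probes, spot flags, each array alone, the variance moderation, a mean over all probes of a gene, the set test and the threshold. A count was taken as moved when it differed by more than a factor of 1.5.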

Results

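Gene expression in leaves of 4-week-old rice seedlings was compared between a mutant of OsRDR1, which encodes an RNA-dependent RNA polymerase of the RNA silencing machinery, and the wild type. There were 2 arrays, each holding both genotypes, with the dyes swapped between them. On replicate 1, 73.1% of spots that were not controls were well above background in Cy3 and 74.8% in Cy5. On replicate 2 these shares were 70.4% and 76.1%. All ratios are log2 of mutant over wild type, given as the mean of the 2 arrays ± SD (n = 2), and adjusted p-values come from limma.

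The first comparison asked whether the transcript of the mutated gene itself differed. The single probe for OsRDR1 (Os02g0736200) gave ratios of -0.18 on replicate 1 and -0.41 on replicate 2, a mean of -0.29 ± 0.16 with an adjusted p of 0.0557, which did not pass the threshold. The wild-type signal was well above background on 2 of 2 arrays and the mutant signal on 1 of 2. The labels used here do not give the position of the mutation, so this probe does not check the genotype labels. The call was gained with an offset of 10, where the ratio was -0.48, and with no background correction and a trend in eBayes, at -0.29 each. Over the alternatives the ratio ranged from -0.16 with median centring to -0.74 with the scanner software's ratios and with the authors' value table, none of which passed, and the adjusted p from 0.00833 to 1.00.

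Among the other silencing genes, AGO18 (Os07g0471300, described on the array as an Argonaute 4 protein) fell, with a ratio of -0.64 ± 0.05 and an adjusted p of 0.000218. None of the other 18 measured members of the RNA silencing list, which also holds the Dicer-like proteins that process double-stranded RNA, passed the threshold in limma. At an unadjusted p under 0.05 the list held 4 higher and 4 lower genes. Ratios were 0.11 for RDR2 (Os04g0465700), 0.27 for DCL1 (Os03g0121800), -0.28 for DCL2a (Os03g0583900), 0.26 for AGO1b (Os04g0566500) and -0.30 for AGO4b (Os04g0151800). Adjusted over the list alone the count was also 1 lower and 0 higher. With a trend in eBayes AGO4b, AGO1b, DCL1 and AGO1d (Os06g0729300, 0.26) passed too. AGO4b also passed with no background correction and with signal required in both channels, and AGO1d with gene means. AGO3 (Os04g0615800), at 0.28, passed with an offset of 10 (0.41), the scanner software's ratios (0.55) and the authors' value table (0.55). The list median was 0.00 and its mean -0.02, and camera pointed down with an adjusted p of 0.969, a direction that turned with the scanner software's ratios. Of 4 DNA methylation genes, MET1b (Os07g0182900) fell, at -0.43 ± 0.42, with -0.13 on replicate 1 and -0.73 on replicate 2, and it was the 1 called when adjusted over the list alone. The median of this list was 0.04, its mean -0.05 and its test pointed down with an adjusted p of 0.969. None of 3 measured MADS-box genes targeted by miR444 passed in limma, either over all probes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05, with MADS27 (Os02g0579600) at -0.25 and an adjusted p of 0.932 for the list. Of 86 transposable element genes, 5 rose and 5 fell (5 and 4 adjusted over the list alone), with a median of 0.05 and an adjusted p of 0.282. A retrotransposon gag gene (Os12g0428300) fell by 2.60 on the log2 scale and an En/Spm-like gene (Os07g0431000) rose by 0.79. In the mutant, Os12g0428300 and MET1b were each well above background on only 1 of 2 arrays.

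Among annotated genes, the largest increases in the mutant were in a lipid transfer protein gene (Os05g0160300, 4.32 ± 0.08), a ferric reductase-like gene (Os04g0578600, 3.61 ± 0.17), a gene for a physical impedance induced protein (Os03g0718800, 3.49 ± 0.44) and a beta-tubulin gene (Os05g0413200, 3.42 ± 0.15, with 2.70 at its other probe). A metallothionein gene (Os05g0202800) rose by 2.68, and the cold-response regulators DREB1B (Os09g0522000) and DREB1A (Os09g0522200) rose by 2.08 and 1.99. Also among the 12 highest annotated genes were a WD40-like gene (Os05g0169200, 2.29), the root-specific protein gene RCc2 (Os04g0612500, 2.16), an FtsH protease gene (Os06g0229000, 2.12), an aspartic peptidase gene (Os06g0118700, 2.01) and a gene described as TGF-beta receptor-like (Os02g0689900, 2.01). Os06g0118700 was well above background in the wild type on only 1 of 2 arrays.

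The largest decreases among annotated genes were in a ribonuclease P-related gene (Os05g0270500), a transferase gene (Os12g0458100, -3.93 ± 0.11), a beta-glucosidase aggregating factor gene (Os12g0247700, -3.06 ± 0.55) and phenylalanine ammonia-lyase 2 (Os04g0518400, -2.87 ± 0.06), which opens the phenylpropanoid pathway. Os05g0270500 was not well above background in the mutant on either array and was at least 17.7-fold lower there, with an adjusted p of 4.20e-14. PR1a (Os07g0129200, -2.65), a lipoxygenase gene (Os12g0559200, -2.46), a gene described as WRKY50 (Os11g0117600, -2.45), a terpene synthase gene (Os08g0168000, -2.29), the peroxidase POC1 (Os07g0677500, -2.26) and an endochitinase gene (Os06g0726100, -2.22) were also among the 12 lowest annotated genes. Loci described as hypothetical proteins, such as Os12g0117700 at -3.31 and Os07g0511400 at 2.54, chosen after their values were seen, lay between them. An amylase/trypsin inhibitor gene (Os03g0661600) gave -2.36 with the probe used and -0.63 with its other probe. The SD between arrays was at most 0.55 for the genes named here and in the groups that follow, apart from 3 loci whose SD is given.

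**Figure D1:**
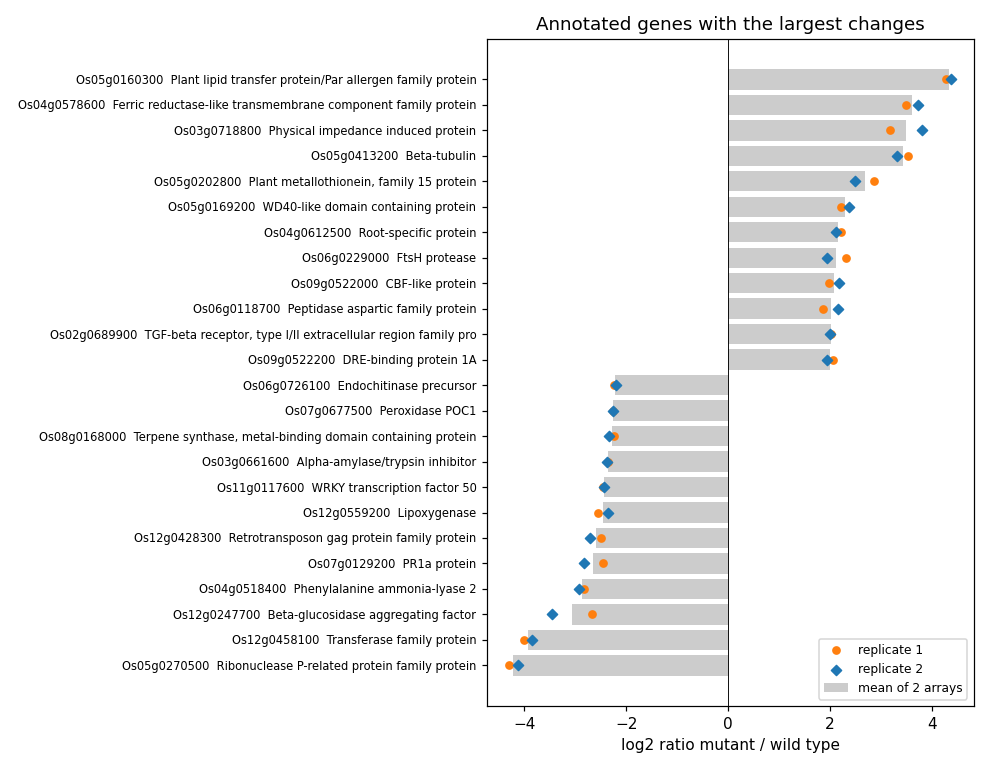
The 12 annotated genes highest and the 12 lowest in the mutant, past the threshold and with the same sign on both arrays. Bars give the mean log2 ratio of mutant over wild type on 2 arrays, circles and diamonds give replicates 1 and 2, and the lowest bar is the fitted ratio of Os05g0270500, which was at least 17.7-fold lower.

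In total 3889 probes were called higher and 4521 lower of 31487 tested, or 2472 and 3135 of 21390 genes. Of the called probes, 70.4% differed by less than 1.5-fold. At least 2-fold the same way on both arrays were 180 probes higher and 205 lower, and 0 probes were 2-fold apart in opposite directions. The arrays' ratios correlated with a Pearson r of 0.784 and a Spearman rho of 0.676 across probes, which are not independent replicates, and 72.5% of probes had the same sign. Of the called probes 11 had opposite signs on the arrays. By replicate 1 alone 279 probes were at least 2-fold higher and 300 lower, and by replicate 2 alone 270 and 349. The counts depend on the processing: median centring in place of loess left 264 probes called higher and 330 lower, with r at 0.356, and the scanner software's ratios gave 2130 and 2461.

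**Figure D2:**
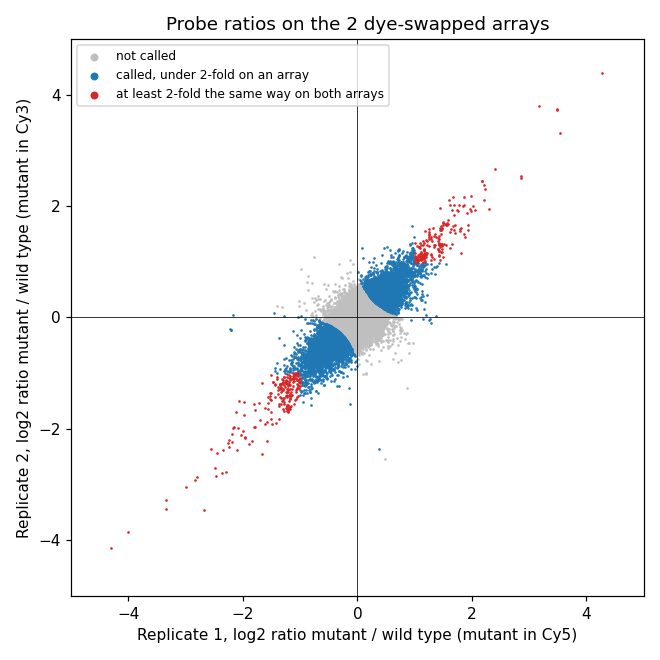
Each point is a probe, with its log2 ratio of mutant over wild type on replicate 1 (horizontal axis) and on replicate 2 (vertical axis). Red points are the 180 and 205 probes at least 2-fold higher or lower on both arrays, blue points are other called probes and grey points were not called.

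Genes for pathogenesis-related proteins and for WRKY factors were lower in the mutant more often than higher. The lists were not split by what their members do in defence. Of 83 measured genes for pathogenesis-related proteins, 41 fell, 8 rose and 34 did not pass (42 lower and 10 higher adjusted over the list alone), with a median of -0.31. Beside PR1a, the PR10 gene JIOsPR10 (Os03g0300400) fell by 2.15, though its 2 probes lay 1.15 apart, and a PR1 gene (Os07g0129300) fell by 2.06. Of 57 WRKY transcription factor genes, 25 fell and 6 rose (26 and 8 adjusted over the list alone), among them WRKY76 (Os09g0417600, -1.08) and WRKY62 (Os09g0417800, -1.08), with a median of -0.20. Camera called both lists lower, with adjusted p of 2.19e-07 and 4.74e-04. With an estimated correlation, which leaves 1 degree of freedom, the adjusted p = 0.650 for each. Over the alternatives the medians ranged from -0.37 to -0.070 and from -0.29 to -0.11, nearest to 0 with no filter on dim probes.

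Genes that make defence compounds were also lower more often than higher, as were those of a list of jasmonate synthesis and its repressors. Of 12 genes of diterpenoid phytoalexin synthesis, 8 fell and 2 rose, with the same counts adjusted over the list alone and a median of -0.66. They included the terpene synthase KSL7 (Os02g0570400, -1.30, with -0.74 at its other probe), CYP99A3 (Os04g0178400, -0.85) and MAS (Os04g0179200, -0.85). The genes that rose, chosen after their values were seen, were CPS2 (Os02g0571100, 0.31) and a kaurene synthase A gene (Os02g0278700, 0.61). Whether the latter acts in phytoalexin synthesis was not checked. Of 30 genes of jasmonate synthesis and its JAZ (jasmonate ZIM-domain) repressors, 15 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -0.31. The list holds 11 genes with a ZIM domain, a family compared after results were seen, and 9 of the 15 that fell were among these. The count for the list is therefore not a count of synthesis genes. The largest decreases were in the lipoxygenase genes Os12g0559200 (-2.46, with probes from -3.39 to -2.46), Os12g0560200 (-2.06), LOX-RCI1 (Os08g0509100, -1.32) and Os12g0560100 (-1.18). The gene that rose, chosen after its value was seen, was another lipoxygenase gene (Os02g0194700, 0.55). Of 45 phenylpropanoid genes, 22 fell and 3 rose (22 and 4 adjusted over the list alone), with a median of -0.26, including a cinnamoyl-CoA reductase gene (Os08g0441500, -1.33) and a chalcone synthase gene (Os07g0526400, -1.31). Camera called the 3 lists lower, with adjusted p of 1.70e-04, 6.87e-07 and 6.44e-07, and an adjusted p = 0.650 with an estimated correlation for each. The phenylpropanoid median ranged from -0.36 to -0.090 over the alternatives, nearest to 0 with no filter on dim probes.

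Peroxidase and cytochrome P450 genes moved both ways. Of 114 peroxidase and glutathione transferase genes 40 fell and 18 rose (48 and 18 adjusted over the list alone), with POC1 at -2.26 and a gene for peroxidase 47 (Os08g0113000) at 1.79. Of 158 cytochrome P450 genes 54 fell and 22 rose (58 and 27 adjusted over the list alone), from -1.60 (Os07g0482900) to 1.08 (Os07g0520300) among the named members. The medians were -0.13 and -0.10. Camera called both lower with an adjusted p of 0.0204, and with an estimated correlation the adjusted p = 0.650 for each. With no filter on dim probes these calls ended. Over the alternatives the adjusted p ranged from 0.0129 to 0.197 and from 0.0132 to 0.163, and the medians from -0.16 to -0.016 and from -0.14 to -0.021.

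Genes of the photosystems and light-harvesting complexes were mostly higher. Of 45 measured, 29 rose and 4 fell (31 and 4 adjusted over the list alone), with a median of 0.48. The chlorophyll a/b-binding protein genes Os01g0600900 and CAB2R (Os01g0720500) rose by 1.66 and 1.60. A locus described as the photosystem Q(B) protein (Os04g0236400) was called at -1.21 ± 1.40, a mean that rested on replicate 1, with -2.20 there and -0.22 on replicate 2. The others that fell, chosen after their values were seen, were a locus of like description (Os04g0235200, -1.07 ± 1.56), a 22 kDa protein gene of photosystem II (Os04g0690800, -0.79) and a PsbQ family gene (Os02g0578400, -0.66). Camera gave an adjusted p of 5.39e-09, and an adjusted p = 0.650 with an estimated correlation. Of 18 Calvin cycle genes, 3 rose and 5 fell (4 and 5 adjusted over the list alone). Among those that fell, 3 are described as the Rubisco large chain: Os06g0598500 at -1.14, Os10g0356000 at -0.86 ± 0.71 and Os05g0427800 at -0.49. Whether these loci, or those described as the photosystem Q(B) protein, report separate transcripts was not checked, though each was counted as a gene. The median of this list was 0.07 and its mean -0.09, and the test pointed down with an adjusted p of 0.898, a direction that turned under median centring.

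Ribosomal protein genes were lower in the mutant far more often than higher, mostly by a small amount. Of 295 measured, 139 fell and 1 rose (159 and 2 adjusted over the list alone), with a median of -0.29, with L17 (Os02g0814700) at -0.71 and L30 (Os01g0812800) at -0.65. The gene that rose, chosen after its value was seen, encodes the plastid-specific protein PSRP-1 (Os03g0856500, 0.43). Camera gave an adjusted p of 1.20e-12, and an adjusted p = 0.650 with an estimated correlation.

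**Figure D3:**
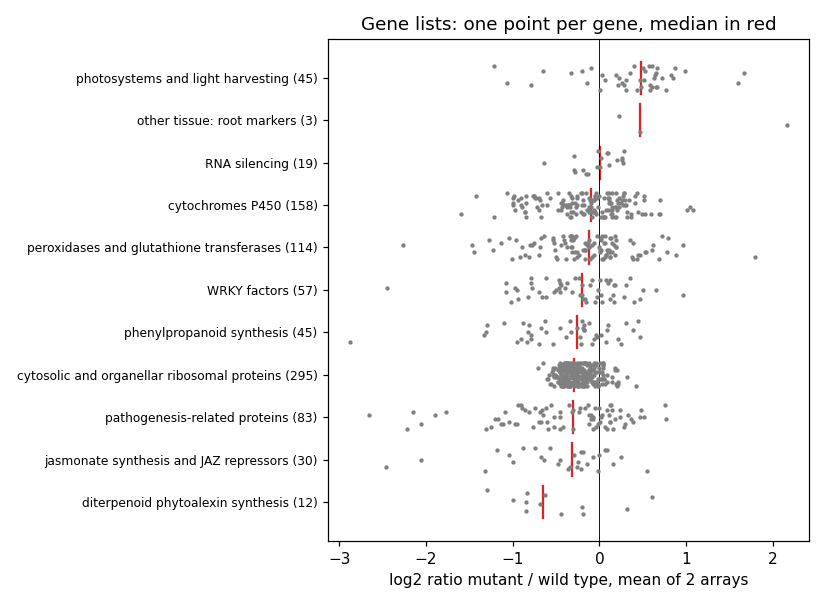
Members of the 10 gene lists called by camera and of the RNA silencing list, with the number measured in brackets. The horizontal axis is the log2 ratio of mutant over wild type as the mean of 2 arrays, each grey point is a gene and red lines are medians, from -0.66 for diterpenoid phytoalexin synthesis to 0.48 for the photosystems.

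Markers of other tissues were measured beside these groups. Of 3 root markers 2 rose, over all probes and adjusted over the list alone: RCc2 (Os04g0612500, 2.16) and a root-specific metal transporter gene (Os01g0503400, 0.46), while RCc3 (Os04g0554600) was at 0.23. Camera gave an adjusted p of 0.00330 for this list, and an adjusted p = 0.650 with an estimated correlation. The call ended with no filter on dim probes, and over the alternatives the adjusted p ranged from 1.34e-05 to 0.0829 and the median from 0.11 to 0.55. Of 11 seed storage protein genes 0 rose and 2 fell, with the same counts adjusted over the list alone and at an unadjusted p under 0.05 in limma: Os03g0661600 and a glutelin gene (Os08g0482300, -0.55). Of 16 meristem and flower markers 3 rose and 3 fell (4 and 3 adjusted over the list alone), with MADS15 (Os07g0108900) at 0.54. The adjusted p for these 2 lists were 0.443 and 0.651.

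Nutrient genes included some large changes within lists that did not pass. Of 14 iron uptake genes 5 rose and 4 fell, with the same counts adjusted over the list alone. The nicotianamine synthase genes NAS2 (Os03g0307200) and NAS1 (Os03g0307300), whose product chelates iron, rose by 1.51 and 1.35, the regulator IRO2 (Os01g0952800) rose by 0.72, and a ferritin gene (Os12g0106000) fell by 0.47. Of 36 nitrate and ammonium genes 10 rose and 5 fell, with the same counts adjusted over the list alone, among them a nitrate transporter gene (Os10g0554200, 1.75, with 0.98 at its other probe) and an ammonium transporter gene (Os03g0838400, -0.90). Of 39 phosphate starvation genes 5 rose and 13 fell (7 and 13 adjusted over the list alone), with a purple acid phosphatase gene (Os01g0776600) at -1.05. The adjusted p of the 3 lists were 0.263, 0.264 and 0.263.

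The remaining lists did not pass either. Of 12 clock and flowering genes 2 rose and 4 fell (2 and 5 adjusted over the list alone): the morning gene LHY (Os08g0157600) rose by 0.50, and LUX (Os01g0971800), FKF1 (Os11g0547000) and TOC1 (Os02g0618200) fell by 0.94, 0.52 and 0.44. Of 41 water-deficit genes 4 rose and 11 fell, with the same counts adjusted over the list alone, and the dehydrin Rab16A (Os11g0454300) fell by 0.81 while DREB1A and DREB1B rose. Of 71 auxin response genes 16 rose and 7 fell (18 and 7 adjusted over the list alone), with a SAUR gene (Os09g0546000) at 1.46 and a GH3 gene (Os07g0592600) at -1.41. Of 88 cell cycle genes 17 rose and 7 fell, with the same counts adjusted over the list alone. The adjusted p of these 4 lists were 0.461, 0.461, 0.0662 and 0.0744, and the last ranged from 0.0459 to 0.163 over the alternatives, passing with the scanner software's ratios and the authors' value table. The cell cycle list had the most loci dropped by description, 378, and with none dropped, an alternative chosen after seeing the data, 338 genes were measured and the adjusted p was 0.159.

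Of 194 NB-ARC resistance-type genes 20 rose and 36 fell (20 and 38 adjusted over the list alone), with Os07g0130700 at -1.14 and Os05g0280700 at 0.95. Of 152 heat shock and chaperone genes 15 rose and 19 fell (14 and 18 adjusted over the list alone), with an Hsp20 gene (Os06g0253100) at 0.90. Of 41 histone genes 3 rose and 7 fell, with the same counts adjusted over the list alone, and an H4 gene (Os02g0684500) rose by 0.90. Of 14 senescence genes 4 rose and 7 fell, with the same counts adjusted over the list alone, and the chlorophyll breakdown gene SGR (Os09g0532000) fell by 0.52. The adjusted p of these 4 lists were 0.152, 0.969, 0.261 and 0.761. With an estimated correlation camera called none of the 10 lists, and 0 lists were under 0.05 before adjustment too. That test had 1 residual degree of freedom. Calls were lost there also for the WRKY, jasmonate and phenylpropanoid lists, whose estimated correlations of -0.018, -0.034 and -0.022 lay below the preset 0.01. Whether the calls hold for correlated genes stays open. With fry, which also had 1 residual degree of freedom and whose smallest adjusted p was 0.144, 0 lists passed and 8 were under 0.05 before adjustment. In either direction fry called 22 lists.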

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

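No test was run for this part. Among probes that no comparison used, 2 of 36 rice control probes were well above background in most of their spots in both channels on both arrays. Counted by spot in a single channel, at most 1.96% of negative control spots were, and at most 11.9% of rice control spots. The share of random-sequence spots reached 20.0%, in Cy5 on replicate 1.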

How the results depend on the processing

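The lists with no locus dropped are an alternative chosen after seeing the data. With 1 array a ratio lies within 1 SD of the mean of 2 by construction, and there is no test, so single arrays say nothing about stability. They gave 270 to 279 probes at least 2-fold higher, 300 to 349 lower, and -0.41 to -0.18 for OsRDR1. Median centring in place of loess gave 264 probes called higher and 330 lower, 111 and 131 at least 2-fold higher and lower on both arrays, and an array correlation of 0.356; 593 of its calls were also called with loess. It left array medians of 0.15 and -0.20, an opposite shift that adds to the spread between arrays, with a median of the mean ratio of 0.0016. The scanner software's processed signals gave 2130 and 2461 calls, 4158 of them shared, and 400 and 491 probes at least 2-fold higher and lower. The authors' value table gave 2069 and 2394 calls, 4061 of them shared, and 399 and 491. The cause was not tested for these. A mean over all probes of a gene gave 2375 and 2930 calls and 105 and 131 at least 2-fold higher and lower, counting genes in place of probes. OsRDR1 passed the threshold with no background correction (-0.29), an offset of 10 (-0.48) and a trend in eBayes (-0.29). Over the alternatives its ratio ranged from -0.74 to -0.16 and its adjusted p from 0.00833 to 1.00; the cause was not tested. The 10 list calls became 0 with an estimated correlation, which leaves 1 degree of freedom. They became 0 with fry too, which also has 1 and asks another question.

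Some results that were not called turned direction, and the cause was not tested. Os02g0169400 was at 0.054 with no background correction, 0.16 with the processed signals, 0.16 with the value table and 0.035 with median centring, where AGO2 (Os04g0615700) was at -0.034 and SHL2 (Os01g0527600) at -0.030. Camera's direction turned for RNA silencing with the processed signals (median 0.040), the value table (0.040), signal in both channels (0.0087) and gene means (0.0020). It turned for the Calvin cycle with median centring (0.22), no dim-probe filter (0.065) and gene means (0.069), for heat shock proteins with the processed signals (-0.0037) and the value table (-0.0037), for water deficit with median centring (-0.12), and for DNA methylation with signal in both channels (0.091). With no locus dropped 10 lists were called, and the median of pathogenesis-related proteins was -0.12. Of 134 named genes beside OsRDR1, 49 lost their call under median centring, 15 with the value table and 14 with the processed signals. The separate-channel fit with a dye term could not be fitted, no spot was saturated, camera has no robust option, and OsRDR1 has no value where signal is required in both channels. Signal over background limits OsRDR1 and other dim probes.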

Other observations

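The test of dye bias, its repeat under other settings, the family comparison and the counting spread asked of the test of tandem families were chosen only after the result was seen. Of 155 families of at least 10 genes sharing 1 description, camera called 1 higher and 1 lower. Of 16 rhodanese-like genes 7 rose, with a median of 0.28 and an adjusted p of 0.00996. Of 11 genes with a ZIM domain, all members of the jasmonate list, 9 fell, with a median of -0.48 and an adjusted p of 0.00598. With an estimated correlation the adjusted p = 0.956 for both.

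Of 510 probes named for miRNA loci, 128 were measured. Of these 25 were called higher and 2 lower, against 3889 and 4521 of all 31487 probes tested. The 510 hold 170 probes for mature miRNAs and 340 for precursor flanks. Over all spots of these classes the median Cy5 signals were 66.7 to 74.6, near the 68.6 and 71.5 of random-sequence probes. Whether miRNAs themselves changed was not tested.

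Probes at least 2-fold apart on both arrays numbered 385. Gene-specific dye bias could produce large ratios, but with the dyes swapped it would give opposite directions once both arrays are turned the same way, and 0 probes were 2-fold apart in opposite directions, with an upper 95% bound of 0.954%. With an offset of 10 there were 11 such probes beside 540 in the same direction, and 60 beside 891 with the processed signals (6.73%, above the 5% bound of the test) and 60 beside 890 with the value table. A difference between the plants used, other than the genotype, stays open and was not tested.

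The transcript of the root-specific protein gene Os04g0612500 was higher by 2.16. Root tissue in the mutant leaf sample may be a source. Of 9 loci in the root list, 3 were measured, and these 3 were well above background in wild-type leaf too. The higher of the 2 arrays' medians of the other 2 root markers was 0.345, below the 0.5 set in advance. Their SD of 0.198, a margin that the bound set in advance did not ask for, reaches 0.5. Of these markers, Os01g0503400 gave 0.46 with the probe used and 0.19 with the lowest of its 4 probes. With 2 markers, root tissue cannot be told apart from a change in the leaf.

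The 244 genes at least 2-fold apart formed 49 pairs at most 10 measured genes apart, against a mean of 27.7 and a highest value of 48 in 10000 random placements. Tandem gene families may account for part of this: without genes of like description 40 pairs remained, above 36, the upper percentile of random placements set in advance, and the ratio to random placement was 1.54, against 1.77 with them. This met the bound of 1.5 set in advance against such families as the whole account, but by less than the counting spread, and pairs such as PR1a and its neighbour keep different descriptions, so their share stays open. A chromosome segment linked to the OsRDR1 locus could also carry such genes. Among 200 measured genes beside OsRDR1, 2% were at least 2-fold apart (95% exact interval 0.548% to 5.04%), against 1.13% elsewhere, with a Fisher's exact p of 0.295, which leaves a 3-fold excess neither shown nor excluded. Only 4 of the 244 genes lay in this stretch, so it was not the source of most of the pairs. All 4 fell: Os02g0718100 (-1.32), Os02g0718600 (-1.19), Os02g0719600 (-2.07) and Os02g0730000 (-1.11). The first 3 lay within 10 measured genes of each other. Chromosome 2, which carries OsRDR1, had the lowest share of any chromosome (0.72%). A share over the whole chromosome does not describe the stretch beside OsRDR1, so whether a linked segment holds some of the pairs stays open.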
